A study of Zea mays with 12 samples.

How the data were processed

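Stranded mRNA libraries had been made from the emerging leaf 4 of 14-day-old greenhouse-grown maize, cultivar Golden Queen. There were 4 libraries each for 10-OPEA, 12-OPDA and the carrier control. The FPKM values were used as deposited by the authors, 1 column per library for 39604 gene IDs, of which 9066 stood at 0 in every library. Per the labels, reads had been trimmed with Trimmomatic 0.32 and the genome build was B73 RefGen_v3. The aligner, the quantifier and the annotation release are not given in the sources used here. The table holds no counts, so the planned count-based tests were not run. Its column names write 12-OPDA as 12-OPEA, and the deposited description of the columns pairs those columns with the 12-OPDA samples, which was followed here. The labels give no dose, no treatment time and no carrier for the treated samples, and do not say whether replicates were separate plants.

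The column totals differ between libraries. Depth could be estimated only relative to the deepest library, from the value of single fragments in genes at or under 0.15 FPKM. Of 1901 genes with a median of at least 50 FPKM, 5 were listed at 0 in at least 1 library.

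Genes with a mean of at least 1 FPKM over the 12 libraries were tested (17793 genes). Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with group as the only term, all 12 libraries sharing 1 estimate of the spread, and empirical Bayes with a mean-variance trend. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Intervals are 95% intervals from the same fit. The comparisons were each compound against control and the compounds against each other. For the response shared by the compounds, the common controls were allowed for with 20 simulated sets of unchanged groups and with the controls split 2 and 2. In the simulated sets all libraries, controls included, were drawn around the control means, each gene independently. The split was run as 6 ordered assignments, since each pair of controls can serve either compound.

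Gene symbols came from a reference gene table of another build (Zm-B73-REFERENCE-NAM-5.0), used for names only. Of the 39604 gene IDs 19059 matched a gene there, 521 of them more than 1, and 2812 carried a symbol. Of the tested genes 12744 matched and 1819 carried a symbol, so list members are the named part of each family. The 43 gene lists were written as symbol patterns, and 33 had at least 5 measured members, 6 had 1 to 4 and 4 had none. Lists with at least 5 were tested with camera at a preset correlation of 0.01, adjusted over 99 tests, and again with an estimated correlation. Members called were also counted with p-values adjusted over the list alone. The lists reported first were oxylipin biosynthesis, jasmonate signalling, glutathione transferases, cytochrome P450, UDP-glycosyltransferases, heat shock proteins and factors, protease inhibitors, pathogenesis-related proteins, and photosystems and light harvesting. Marker lists covered mesophyll, bundle sheath, epidermis and cuticle, vascular tissue, dividing cells, seed storage, and pollen and anther. Symbol patterns also took in 33 members of other gene families, most of them phosphatases in the vascular list.

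Genes were named by a rule. In each comparison these were the 6 largest increases and 6 largest decreases among called genes with a symbol and no overlap between the groups, and the 2 members of each leading list with the smallest p-values. Oxylipin and defence genes chosen by symbol, such as *aos1*, *opr7*, *bx1* and *wip1*, were added where measured. In other called lists the 2 members with the smallest p-values were named. The tests, thresholds, lists, naming rule and first set of alternatives were chosen before the data were examined.

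The alternatives were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, only the 2 groups compared, no mean-variance trend, robust fitting with array weights, replicate numbers as blocks, at least 2-fold change, and leaving out each library in turn. Chosen after the data were seen were fry in place of camera, longer lists that also match full synonyms, lists without members of other gene families, and leaving out 12-OPDA replicate 3 with 10-OPEA replicate 4. The fit was tested on simulated data, 5 sets of 17793 genes with 200 changed per compound. It recovered 72.9%, 68.2% and 77.9% of 2-fold changes with 10-OPEA, with 12-OPDA and between the compounds, and 12.9%, 14.4% and 20.7% of 1.5-fold changes. Of its calls 5.75%, 5.68% and 4.47% were on unchanged genes. All 10 tests on a list raised 2-fold were called and 0 others. The simulated genes varied independently, so this list result does not carry over to lists with correlated members. Far fewer genes changed than were called in the data, so the recovery rates may also differ there.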

Results

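The study measured mRNA in maize leaves treated with either of 2 cyclopentenone fatty acids. Leaves came from the sweet corn cultivar Golden Queen at stage V-3, 14 days old, and the tissue was the fourth leaf while it was still emerging. The first compound, 10-OPEA (10-oxo-11-phytoenoic acid), belongs to the group that the series title calls death acids. It derives from linoleic acid through the 9-lipoxygenase route. The second compound, 12-OPDA (cis-12-oxo-phytodienoic acid), derives from linolenic acid through the 13-lipoxygenase route and is the precursor of jasmonic acid, the wound hormone. Both carry a cyclopentenone ring, an electrophilic group that reacts with thiols. Control leaves received the carrier, 5% DMSO with 0.1% Tween 20 in water. The doses and the time between treatment and harvest are not given in the sources used here, so the compounds cannot be compared at a known common dose.

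There were 12 libraries, 4 for each compound and 4 for the carrier control. The deposited table gives FPKM (fragments scaled to gene length and to the library's total), so the absolute depth of each library is unknown. FPKM summed to between 623815 (control replicate 4) and 800109 (control replicate 1), and between 23166 and 26399 genes stood above 0 in a library. Steps in the low values placed the relative depth of the libraries between 0.285 (12-OPDA replicate 3) and 1 (10-OPEA replicate 1). The 10 most abundant genes took 9.78% to 14.4% of a library's summed FPKM. Across genes, log2(FPKM + 1) correlated at 0.942 to 0.979 between libraries of 1 group. The range was 0.922 to 0.964 between the compounds and 0.785 to 0.915 between control and treated libraries. No pair of libraries held identical values. All changes below are differences of log2(FPKM + 1) with their standard errors, from limma with Benjamini-Hochberg adjusted p-values and n = 4 libraries per group. The added 1 makes this scale understate the change of genes near 0. The labels do not say that replicates were separate plants, so the p-values measure only the spread between these samples.

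**Figure D1:**
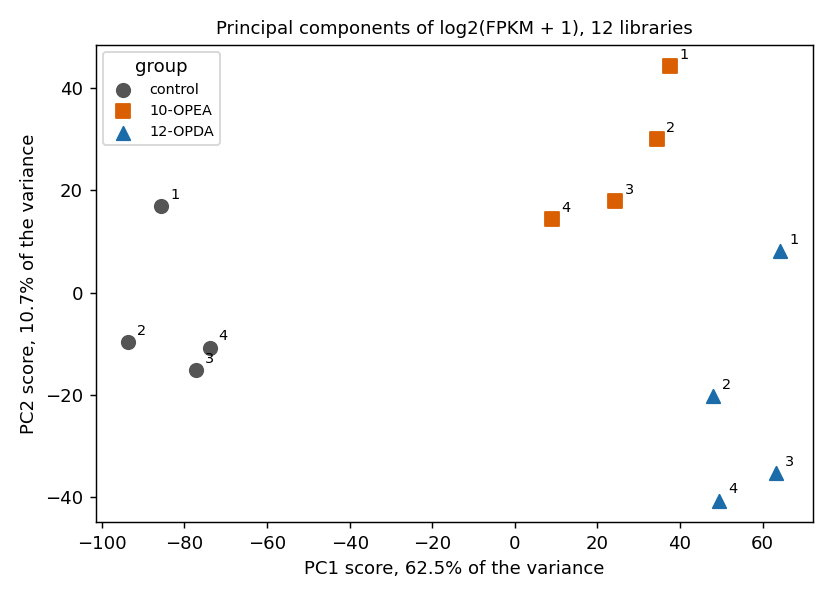
Scores of the 12 libraries on the first principal components of log2(FPKM + 1). The horizontal axis carries 62.5% of the variance and the vertical axis 10.7%, each point is a library and its number is the replicate. Control libraries lie at PC1 scores of -93.6 to -73.9, 10-OPEA libraries at 8.99 to 37.7 and 12-OPDA libraries at 47.97 to 64.2.

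The comparison of 10-OPEA with the carrier control asks which transcripts this 9-lipoxygenase product changes in a leaf. The largest increases among named genes were in molecular chaperones. *hsp101* (GRMZM2G360681), which encodes a disaggregase of the ClpB class, stood at 0.475 ± 0.124 FPKM (SD) in control leaves and 199 ± 30.8 FPKM with 10-OPEA, a log2 change of 7.07 ± 0.16 (adjusted p = 1.4e-11). The Hsp90 gene *hsp82* (GRMZM5G833699) rose by 6.51 ± 0.17 (adjusted p = 2.7e-11), from 0.223 ± 0.139 to 110.5 ± 15.6 FPKM. The small heat shock protein genes *hsp18f* (GRMZM2G083810) and *hsp22* (GRMZM2G007729) rose by 6.95 ± 0.20 and 6.31 ± 0.27, and *Hsp70* (GRMZM2G310431) rose by 6.13 ± 0.24. Most measured genes of oxylipin synthesis (18 of 21), jasmonate signalling (8 of 9) and glutathione conjugation (15 of 24) rose as well, with adjusted p = 0.232, 0.246 and 0.232 for these lists with an estimated correlation.

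Of 17793 genes tested, 5516 changed with 10-OPEA, 3284 upward and 2232 downward. A change of at least 2-fold was estimated for 1848 of those that rose and 439 of those that fell. At least 4-fold changes numbered 675 upward and 16 downward. Quantile normalization shifted the median of all genes by -0.14 log2 units and turned the split to 2732 upward and 4145 downward, so the balance of directions depends on the scaling. For every gene named below as risen or fallen in this comparison, the 4 treated values all lay on one side of the 4 control values, except *opr6* and *gst18*.

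Among the heat shock proteins and factors, 15 of 20 measured members rose, 1 fell and 4 did not pass the test, with a median change of 3.84. Adjusted over the list alone, 16 rose and 2 fell. As a list the heat shock genes stood above the other genes (adjusted p = 6.6e-13 with camera's preset correlation, adjusted p = 0.214 with an estimated correlation). *hsp18c* (GRMZM2G034157), another small heat shock protein gene, was listed at 0 in 3 control libraries and reached 54.7 ± 10.6 FPKM, a change of 5.70 ± 0.32 (adjusted p = 2.0e-08). The member that fell was *Hsf17* (GRMZM2G125969, -0.91 ± 0.19), a heat shock factor named after its values were seen. Small heat shock protein genes are close in sequence, and how reads shared between copies were assigned is not given in the sources used here.

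Oxylipin biosynthesis, the lipoxygenase routes that also lead to both test compounds, had 18 of 21 members higher, 1 lower and 2 that did not pass, with a median change of 2.51. Adjusted over the list alone, 19 were higher and 1 lower. The list as a whole was called (adjusted p = 1.4e-13, adjusted p = 0.232 with an estimated correlation). Its strongest member by p-value was *opr3* (GRMZM2G156712), a 12-oxo-phytodienoate reductase gene, which rose from 1.54 ± 0.471 to 116 ± 21.3 FPKM, a change of 5.52 ± 0.19 (adjusted p = 3.2e-10). *aos1* (GRMZM2G067225), encoding allene oxide synthase, rose by 4.05 ± 0.21 (adjusted p = 8.7e-09). *aoc1* (GRMZM2G077316), encoding the allene oxide cyclase that follows it, rose by 3.44 ± 0.29 (adjusted p = 1.3e-06). The jasmonate synthesis genes *ts1* (GRMZM2G104843, lipoxygenase LOX8) and *opr7* (GRMZM2G148281) rose by 2.51 ± 0.17 and 1.92 ± 0.15. *opr8* (GRMZM2G082087), the close relative of *opr7*, gave 0.42 ± 0.17 and did not pass (adjusted p = 0.0773). It passed without 10-OPEA replicate 4, at 0.56, and with a robust fit and array weights, at 0.46. *lox10* (GRMZM2G015419), a lipoxygenase of green leaf volatile synthesis, was abundant in control leaves at 3748 ± 1186 FPKM and did not pass either (0.37 ± 0.24, adjusted p = 0.280), although it did with quantile normalization, at 0.55. *opr6* (GRMZM2G068947, -0.60 ± 0.17), singled out after its values were seen, was the member that fell.

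All 5 measured members of the 9-lipoxygenase branch rose, as they did adjusted over the list alone, with a median of 3.66 (adjusted p = 7.8e-05, adjusted p = 0.214 with an estimated correlation). They included *lox3* (GRMZM2G109130, 4.54 ± 0.32) and *lox1* (GRMZM2G156861, 4.49 ± 0.25). In the 13-lipoxygenase branch 9 of 11 members rose and 2 did not pass, with a median of 2.01. The 2 smallest p-values were those of *aos1* and *aos2* (GRMZM2G002178, 3.35 ± 0.19), and adjusted over the list alone 10 rose (adjusted p = 1.5e-08 for the list, adjusted p = 0.246 with an estimated correlation). For jasmonate signalling, mostly TIFY-domain repressors of the jasmonate response, 8 of 9 members rose and 1 did not pass, and 8 rose adjusted over the list alone. Its median was 1.85 (adjusted p = 0.000101, adjusted p = 0.246 with an estimated correlation). *ZIM4* (GRMZM2G036351) went from 9.43 ± 2.17 to 68.8 ± 23.1 FPKM (2.70 ± 0.26) and *ZIM28* (GRMZM2G116614) rose by 1.49 ± 0.17.

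Glutathione transferases join glutathione to electrophiles. Of their 24 measured members 15 rose, 2 fell and 7 did not pass, the same counts adjusted over the list alone, with a median of 1.83 (adjusted p = 1.2e-07, adjusted p = 0.232 with an estimated correlation). *gst2* (GRMZM2G132093) rose from 26.7 ± 2.72 to 729 ± 194 FPKM, by 4.69 ± 0.21 (adjusted p = 3.2e-09), and *gst31* (GRMZM2G475059) by 3.88 ± 0.18. The members that fell were *gst18* (GRMZM2G019090, -0.99 ± 0.27) and *gst10* (GRMZM2G096153, -0.83 ± 0.17), both named after their values were seen. Of 11 reactive carbonyl reductase genes 0 rose and 2 fell, and that list was not called (adjusted p = 0.393 with camera's preset correlation). Of 12 antioxidant and thiol redox genes 3 rose and 2 fell, and that list was not called either (adjusted p = 0.713 with camera). Cytochrome P450 genes had 7 of 9 members higher, 1 lower and 1 that did not pass, over all genes and over the list alone, with a median of 1.12 (adjusted p = 0.0112, adjusted p = 0.30 with an estimated correlation). The leading members were *cyp71c2* (GRMZM2G167549, also BX3, 1.67 ± 0.21) and *CYP71C3* (GRMZM2G063756, also BX5, 1.22 ± 0.16), hydroxylases of benzoxazinoid synthesis. The member that fell, *CYP714B3* (GRMZM2G106408, -0.95 ± 0.27), was singled out after its values were seen. UDP-glycosyltransferases had 4 of 6 members higher and 2 that did not pass, over all genes and adjusted over the list alone, with a median of 1.41 (adjusted p = 0.00551, adjusted p = 0.246 with an estimated correlation). *ciszog1* (GRMZM2G168474), a cis-zeatin O-glucosyltransferase gene, rose by 2.38 ± 0.24. *bx9* (GRMZM2G161335), which glucosylates benzoxazinoids, rose by 1.28 ± 0.18.

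Among defence genes, 11 of 13 benzoxazinoid genes rose and 2 did not pass, also adjusted over the list alone, with a median of 1.54 (adjusted p = 3.6e-07, adjusted p = 0.214 with an estimated correlation). *BX14* (GRMZM2G127418) rose by 3.99 ± 0.29 and *glu1* (GRMZM2G016890), a beta-glucosidase gene, by 2.40 ± 0.19. *bx1* (GRMZM2G085381), whose product makes indole for this pathway, rose by 1.90 ± 0.24, while *igl1* (GRMZM2G046191) gave 0.18 ± 0.21 (adjusted p = 0.552). Of 6 pathogenesis-related genes 5 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 2.23 (adjusted p = 0.0128, adjusted p = 0.419 with an estimated correlation). *pr5* (GRMZM2G402631), a thaumatin-like gene, rose by 2.69 ± 0.31 and *prp4* (GRMZM2G465226), a PR-1 gene listed at 0 in 3 control libraries, by 1.87 ± 0.23. The member that fell, *PRP* (GRMZM2G049915, -0.74 ± 0.14), chosen after its values were seen, also carries the symbol of the splicing factor Sf3a2. It may therefore not be a pathogenesis-related gene, and the results given for this list include it. The call for this list ended with a filter at a mean of 5 FPKM (adjusted p = 0.0726). Protease inhibitors had 3 of 6 members higher and 3 that did not pass, also over the list alone, and the list was not called (median 0.55, adjusted p = 0.107, adjusted p = 0.485 with an estimated correlation). It was called as a longer list that also matches full synonyms (adjusted p = 0.0427) and with fry (adjusted p = 0.00212). *MPI* (GRMZM2G028393), the maize proteinase inhibitor, rose from 263 ± 119 to 1879 ± 566 FPKM, by 2.90 ± 0.35. *wip1* (GRMZM2G156632), a wound-induced Bowman-Birk inhibitor, rose by 2.67 ± 0.46 (adjusted p = 0.000664). *tps10* (GRMZM2G179092), a sesquiterpene synthase of herbivore-induced volatiles, rose by 4.12 ± 0.32. In the list of NAC transcription factors 6 of 11 rose and 5 did not pass, and 6 rose and 1 fell adjusted over the list alone. Its median was 0.45 (adjusted p = 0.0117, adjusted p = 0.246 with an estimated correlation), with *NAC1* (GRMZM2G347043) at 2.42 ± 0.14 and *NAC20* (GRMZM2G180328) at 3.65 ± 0.30.

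Photosystem and light-harvesting genes had 5 of 15 members lower, 1 higher and 9 that did not pass, the same counts adjusted over the list alone. The list was not called (median -0.43, adjusted p = 0.0585, adjusted p = 0.650 with an estimated correlation). *cab48* (GRMZM2G120619), for a chlorophyll a/b-binding protein, fell by 2.00 on the log2 scale (SE 0.27), from 25.6 ± 12.3 to 5.33 ± 1.46 FPKM. The member that rose, *psat1* (GRMZM2G300801, 1.78 ± 0.31), encodes phosphoserine aminotransferase and is not a photosystem gene. The results given for this list include it. Other large decreases were in *LAC1* (GRMZM5G842071, -2.08 ± 0.31), the aquaporin gene *pip2-5* (GRMZM2G178693, -1.98 ± 0.21), the dehydrin gene *dhn2* (GRMZM2G373522, -1.83 ± 0.34), *bZIP111* (GRMZM2G073427, -1.72 ± 0.19) and *TPS7* (GRMZM2G019183, -1.67 ± 0.24). The symbol TPS is shared by terpene synthases and trehalose-phosphate synthases.

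**Figure D2:**
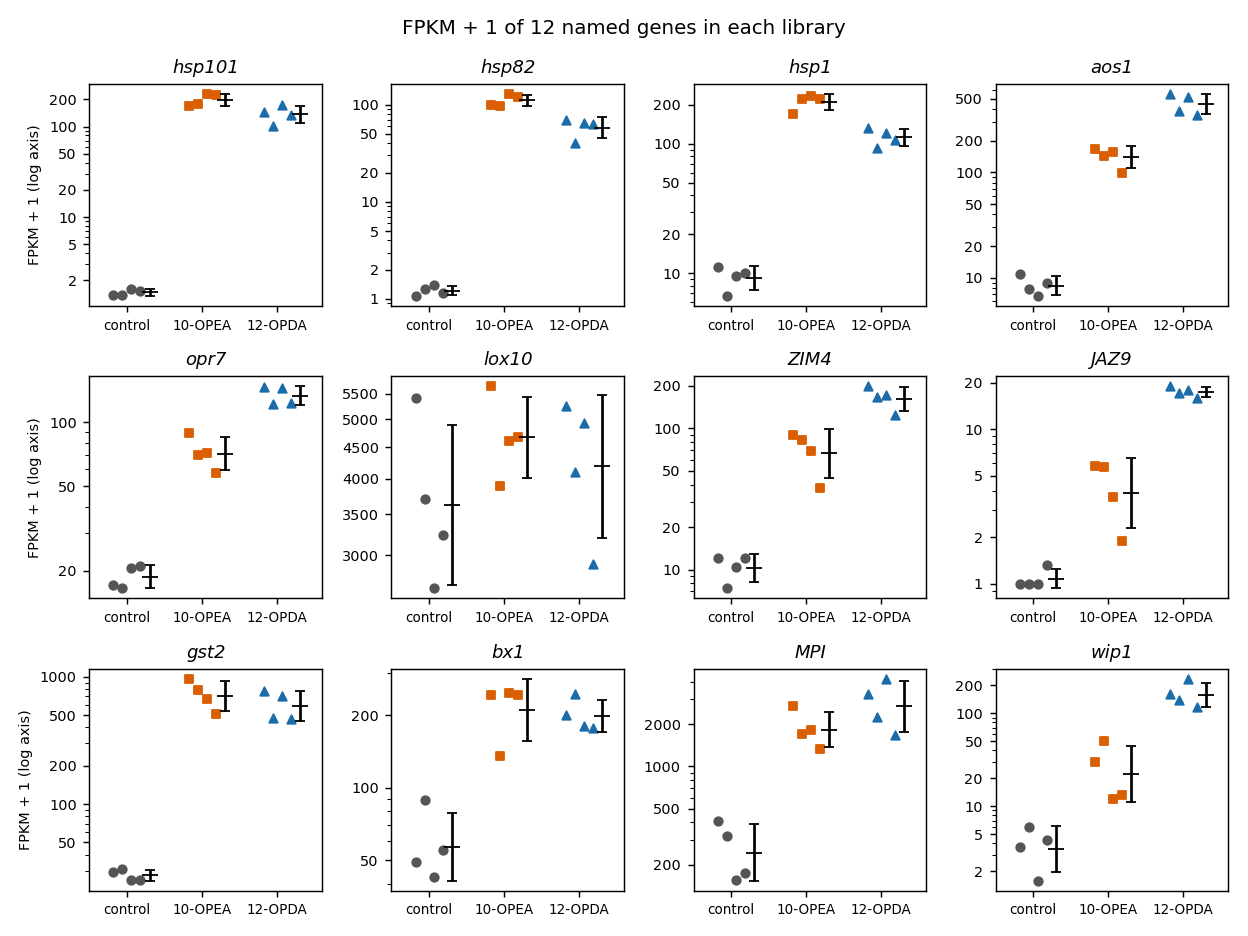
FPKM + 1 of 12 named genes on log axes, each with its own range, in the 4 libraries of each group. Each point is a library, and the black mark and bar beside each group give the mean and 1 SD of log2(FPKM + 1). Control libraries average 0.475 FPKM for *hsp101*, against 199 with 10-OPEA and 138 with 12-OPDA, and *aos1*, *JAZ9* and *wip1* stand higher with 12-OPDA than with 10-OPEA.

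The comparison of 12-OPDA with the carrier control asks the same of the jasmonate precursor. The largest increases in named genes were in chaperones and in genes of other functions. *hsp101* reached 138 ± 29.9 FPKM, a change of 6.53 ± 0.16 (adjusted p = 2.7e-11), and *hsp18f* rose by 6.19 ± 0.20, *Hsp70* by 5.75 ± 0.24 and *hsp82* by 5.58 ± 0.17. The lipoxygenase gene *lox1* rose from 25.8 ± 12.0 to 1517 ± 264 FPKM, by 5.92 ± 0.25 (adjusted p = 1.2e-09). *AAMT1* (GRMZM2G039993), whose product methylates anthranilic acid to a volatile ester, rose from 19.7 ± 11.6 to 1321 ± 120.4 FPKM, by 6.18 ± 0.32. *SPP2* (GRMZM2G097641) rose by 6.32 ± 0.19. The largest decrease among named genes was that of *thi1-2* (GRMZM2G074097), a gene of thiamine thiazole synthesis, from 270.2 ± 129 to 30.8 ± 9.72 FPKM (-3.03 ± 0.37, adjusted p = 2.2e-05).

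In all, 8443 of 17793 genes changed with 12-OPDA, 4037 upward and 4406 downward. With median-of-ratios scaling the split was 4650 upward and 3750 downward, and without control replicates 2 or 3 or 12-OPDA replicate 1 it was 3700 and 3605, 4138 and 4113, and 3871 and 3733, so no balance of directions held across settings. At least 2-fold changes numbered 2263 upward and 1223 downward, and at least 4-fold changes 934 and 81. For every gene named here as risen or fallen, the 4 treated values all lay on one side of the 4 control values, except *igl1*. Besides *thi1-2*, the largest decreases in genes with a symbol were in the MYB-related factors *MYBR47* (GRMZM2G117497, -2.97 ± 0.57), *MYBR41* (GRMZM2G150260, -2.81 ± 0.25) and *RADIALIS* (GRMZM2G114503, -2.57 ± 0.30). *bZIP111* (-2.87 ± 0.19) and *dhn2* (-2.65 ± 0.34) also fell.

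The heat shock list had 16 of 20 members higher, 1 lower and 3 that did not pass, and 16 higher and 1 lower adjusted over the list alone. Its median was 3.44 (adjusted p = 2.2e-10, adjusted p = 0.214 with an estimated correlation). In oxylipin biosynthesis 19 of 21 members rose, 1 fell and 1 did not pass, also 19 and 1 over the list alone, with a median of 3.53 (adjusted p = 1.7e-12, adjusted p = 0.232 with an estimated correlation). *aos1* went from 7.56 ± 1.72 to 453 ± 100.5 FPKM, by 5.72 ± 0.21 (adjusted p = 2.6e-10). *opr3* rose by 5.24 ± 0.19, *aoc1* by 4.82 ± 0.29, *ts1* by 2.96 ± 0.17 and *opr7* by 2.83 ± 0.15. *opr8* passed with a small increase of 0.52 ± 0.17 (adjusted p = 0.0205). That call ended with quantile normalization and without control replicate 2, control replicate 4 or 12-OPDA replicate 3, at changes of 0.45, 0.49, 0.49 and 0.42. *lox10* did not pass (0.21 ± 0.24, adjusted p = 0.503), although it did with quantile normalization, at 0.43. All 5 members of the 9-lipoxygenase branch rose, over all genes and adjusted over the list alone, with a median of 5.01 (adjusted p = 0.000218, adjusted p = 0.214 with an estimated correlation). After *lox1*, its smallest p-value was that of *lox3*, at 5.71. In the 13-lipoxygenase branch 10 of 11 rose and 1 did not pass, as over the list alone, with a median of 2.96 (adjusted p = 1.5e-08, adjusted p = 0.246 with an estimated correlation).

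Jasmonate signalling genes rose in 8 of 9 cases, 1 did not pass, and 8 rose adjusted over the list alone, with a median of 3.87 (adjusted p = 9.8e-06, adjusted p = 0.232 with an estimated correlation). *ZIM4* rose to 164 ± 30.6 FPKM (3.99 ± 0.26) and *ZIM28* to 421 ± 39.1 FPKM (2.43 ± 0.17). For glutathione transferases the counts were 15 higher, 2 lower and 7 that did not pass, also over the list alone, with a median of 1.30 (adjusted p = 6.6e-05, adjusted p = 0.30 with an estimated correlation). *gst2* rose by 4.41 ± 0.21 and *gst31* by 3.97 ± 0.18. Of 11 reactive carbonyl reductase genes 2 rose and 4 fell, and of 12 antioxidant and thiol redox genes 6 rose and 2 fell. Neither list was called with camera's preset correlation (adjusted p = 0.378 and 0.205). Cytochrome P450 genes had 6 of 9 members higher, 1 lower and 2 that did not pass, as over the list alone. Their median was 1.18 (adjusted p = 0.00838, adjusted p = 0.296 with an estimated correlation), led by *cyp71c2* (2.37 ± 0.21) and *CYP71C3* (1.57 ± 0.16). Of 6 UDP-glycosyltransferase genes 4 rose and 2 did not pass, and 5 rose adjusted over the list alone, with a median of 1.16 (adjusted p = 0.0132, adjusted p = 0.280 with an estimated correlation). The cis-zeatin glucosyltransferase genes *ciszog1* and *CISZOG2* (GRMZM2G110511) rose by 2.44 ± 0.24 and 1.66 ± 0.25.

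Benzoxazinoid genes rose in 12 of 13 cases and 1 did not pass, over all genes and the list alone, with a median of 1.63 (adjusted p = 3.6e-07, adjusted p = 0.214 with an estimated correlation). *BX14* rose by 5.71, *Igl* (GRMZM2G046163) by 2.93 and *bx1* by 1.81 ± 0.24. *igl1* passed narrowly at 0.54 ± 0.21 (adjusted p = 0.0486). Its call ended without control replicate 1, 2 or 4, without any single 10-OPEA library, and without 12-OPDA replicate 2, 3 or 4, with changes of 0.33 to 0.59. It also ended with a pseudocount of 0.1, no filter on low values, quantile normalization and a fit of only the 2 groups. Of 6 pathogenesis-related genes 4 rose and 2 did not pass, also over the list alone, with a median of 2.01 (adjusted p = 0.0356, adjusted p = 0.485 with an estimated correlation). The chitinase gene *chn1* (GRMZM2G453805) rose by 2.78 ± 0.33 and *pr5* by 2.46 ± 0.31. The call for this list ended with a filter at a mean of 5 FPKM (adjusted p = 0.0645), with median-of-ratios scaling (adjusted p = 0.0793) and with quantile normalization (adjusted p = 0.0566). Protease inhibitors had 4 of 6 members higher, 1 lower and 1 that did not pass, also over the list alone, and were not called as a list (median 0.56, adjusted p = 0.130, adjusted p = 0.501 with an estimated correlation), but were called as the longer list (adjusted p = 0.0271) and with fry (adjusted p = 0.000377). *wip1* went from 2.86 ± 1.82 to 162 ± 51.2 FPKM, by 5.50 ± 0.46 (adjusted p = 6.3e-07), and *MPI* rose by 3.46 ± 0.35. *tps10* rose by 4.54 ± 0.32. Of 11 NAC factors 7 rose, 2 fell and 2 did not pass, as over the list alone, with a median of 0.69 (adjusted p = 0.0132, adjusted p = 0.246 with an estimated correlation), led by *NAC1* (GRMZM2G347043, 2.50) and *NAC61* (GRMZM2G003715, 3.04). Photosystem and light-harvesting genes had 6 of 15 members lower, 1 higher and 8 that did not pass, also over the list alone, and were not called as a list (median -0.74, adjusted p = 0.105, adjusted p = 0.716 with an estimated correlation). *PSA2* (GRMZM2G021687) fell from 308 ± 49.2 to 167 ± 24.8 FPKM (-0.87 ± 0.15), and the member that rose was again *psat1* (1.84 ± 0.31).

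The responses to the compounds overlapped widely. Of the genes tested, 4789 were called in the same direction with both compounds, 2877 upward and 1912 downward, and 3 in opposite directions. These were 86.8% of the 10-OPEA calls and 56.7% of the 12-OPDA calls. Independent lists of these sizes would share 745.1 genes upward and 552.7 downward. Across genes, which are not independent replicates, the changes correlated at 0.899 with a covariance of 0.798. Both comparisons use the same 4 control libraries, so part of this is built in. Simulated unchanged groups against simulated common controls, drawn 20 times, gave a correlation of 0.497, a covariance of 0.0271 and no shared calls. The covariance above the simulated value was 0.771. Genes were simulated independently, so deviations that a real control library shares across genes are not in the simulated value. With the controls split so that each compound had 2 of its own, the correlation was 0.793 to 0.871, the covariance 0.736 to 0.783 and the shared calls 2476 to 3197. Among the 4789 genes the median ratio of the 10-OPEA change to the 12-OPDA change was 0.839, and 72.4% changed more with 12-OPDA.

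**Figure D3:**
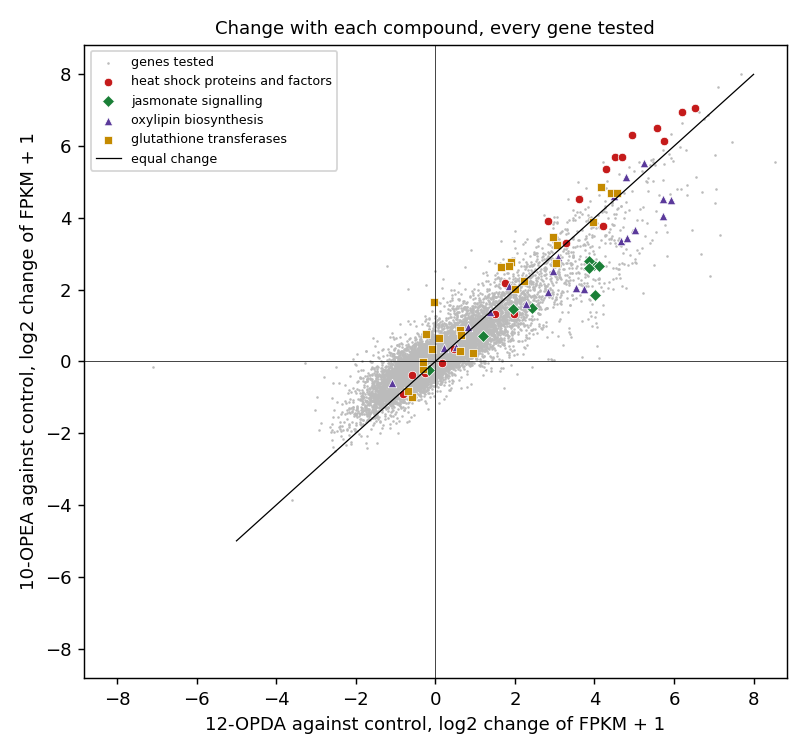
Log2 change of FPKM + 1 with 12-OPDA (horizontal) and with 10-OPEA (vertical), each against the same 4 control libraries, for the 17793 genes tested. Grey points are genes, coloured symbols are members of 4 gene lists and the diagonal marks equal change. The correlation across genes is 0.899, and the 9 measured jasmonate signalling members all lie under the diagonal.

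The direct comparison of the compounds tests where these molecules from different lipoxygenase routes differ in the leaf's response, at doses that are not stated. Of the jasmonate signalling genes 4 of 9 were lower with 10-OPEA than with 12-OPDA, and of the oxylipin biosynthesis genes 9 of 21 (adjusted p = 0.232 and 0.485 for the lists with an estimated correlation in limma's camera). *aos1* was at 141 ± 30.04 FPKM with 10-OPEA and 453 ± 100.5 FPKM with 12-OPDA, a difference of -1.68 ± 0.21 (adjusted p = 0.000333). *JAZ9* (GRMZM2G145407), a jasmonate response repressor listed at 0 in 3 control libraries, was at 3.25 ± 1.85 and 16.5 ± 1.27 FPKM (-2.17 ± 0.29, adjusted p = 0.000598). *wip1* differed by -2.83 ± 0.46 (adjusted p = 0.00256) and *acs7* (GRMZM5G894619), an ACC synthase gene of ethylene synthesis, by -2.56 ± 0.33 (adjusted p = 0.000495). Single genes higher with 10-OPEA included the Hsp90 gene *hsp82* (0.93 ± 0.17, adjusted p = 0.00525) and the glutathione transferase gene *gst20* (GRMZM2G056388, 1.68 ± 0.23, adjusted p = 0.000707).

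Between the compounds 1587 of 17793 genes differed, 776 higher and 811 lower with 10-OPEA, and 232 and 337 of them by at least 2-fold. With median-of-ratios scaling the split was 585 higher and 1192 lower, and with a robust fit and array weights 2558 genes differed, 1375 higher and 1183 lower, so neither direction prevailed across settings. Without 10-OPEA replicate 3, 10-OPEA replicate 4, 12-OPDA replicate 3 or 12-OPDA replicate 4 the count was 966, 987, 930 and 1002. Of the 1587 genes, 1495 were called with at least 1 compound against control. Among those, the estimates against control had the same sign and were larger with 12-OPDA for 1098 and with 10-OPEA for 102, and had opposite signs for 295. A call with each compound was not required for these counts. For every gene named below as higher or lower, the 4 libraries of one compound all lay above the 4 of the other, except *gst8* and *cyp10*.

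Oxylipin biosynthesis genes were lower with 10-OPEA in 9 of 21 cases and 12 did not pass, and adjusted over the list alone 10 were lower and 1 higher. The median difference was -0.45 (adjusted p = 7.8e-05, adjusted p = 0.485 with an estimated correlation). *aos2* differed by -1.32 ± 0.19, *aoc1* by -1.38 ± 0.29 and *opr7* by -0.90 ± 0.15 (adjusted p = 0.00116, 0.0115 and 0.00238 from limma). The difference was not past the threshold for *ts1*, with a 95% interval of -0.81 to -0.09 (it passed with a robust fit and array weights), for *opr8* (-0.47 to 0.25), for *lox10* (-0.37 to 0.68) or for *opr3* (-0.12 to 0.69). In the 13-lipoxygenase branch 7 of 11 members were lower and 4 did not pass, 8 were lower adjusted over the list alone, and the median was -0.90 (adjusted p = 2.7e-07, adjusted p = 0.296 with an estimated correlation). In the 9-lipoxygenase branch 2 of 5 were lower, *lox1* (-1.42 ± 0.25) and *lox3* (-1.18), and 3 did not pass, also over the list alone, with a median of -1.18. That list's call (adjusted p = 0.0361, adjusted p = 0.368 with an estimated correlation) ended with median-of-ratios scaling (adjusted p = 0.0893), quantile normalization (adjusted p = 0.199), no filter on low values (adjusted p = 0.206) and a filter at a mean of 5 FPKM (adjusted p = 0.0535). It also ended without 10-OPEA replicate 3 (adjusted p = 0.0556), 10-OPEA replicate 4 (adjusted p = 0.102), 12-OPDA replicate 1 (adjusted p = 0.123) and 12-OPDA replicate 3 (adjusted p = 0.0551), and without the last and 10-OPEA replicate 4 together (adjusted p = 0.134). Jasmonate signalling genes were lower in 4 of 9 cases and 5 did not pass, 7 were lower adjusted over the list alone, and the median was -1.06 (adjusted p = 1.9e-06, adjusted p = 0.232 with an estimated correlation). *ZIM4* differed by -1.29 ± 0.26 and *ZIM28* by -0.93 ± 0.17.

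**Figure D4:**
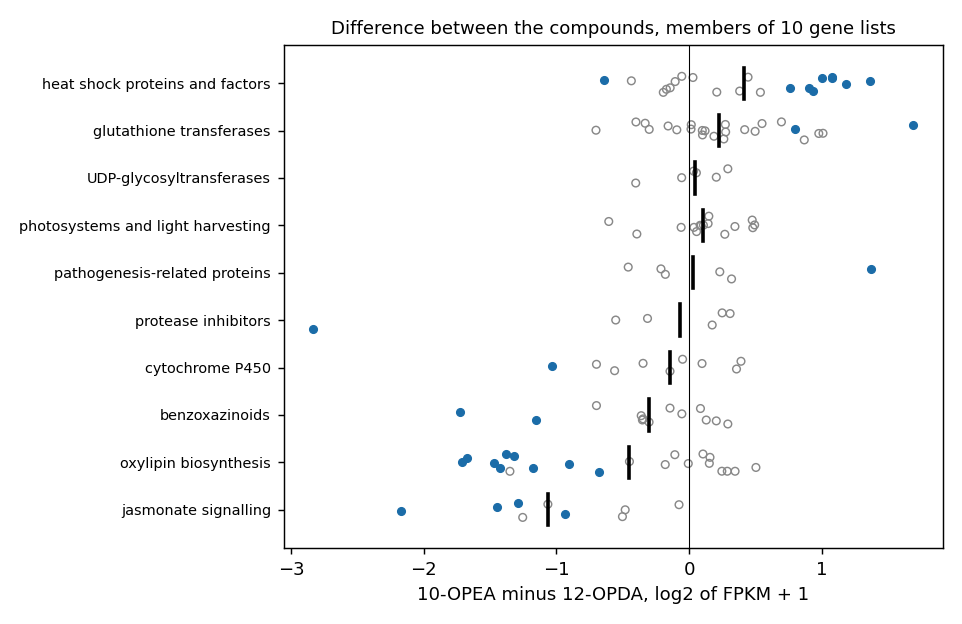
Difference between 10-OPEA and 12-OPDA in log2(FPKM + 1) for the measured members of 10 gene lists, 1 point per gene. Filled points passed the limma test over all genes, open points did not, and black bars are list medians. The medians are -1.06 for jasmonate signalling, -0.45 for oxylipin biosynthesis and 0.41 for heat shock proteins and factors, a list that was not called.

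The heat shock list had 8 of 20 members higher with 10-OPEA, 1 lower and 11 that did not pass, and 9 and 2 adjusted over the list alone. As a list it was not called (median 0.41, adjusted p = 0.0525, adjusted p = 0.564 with an estimated correlation). It was called with fry (adjusted p = 0.0319) and as a longer list that also matches full synonyms (11 of 25 higher, adjusted p = 0.00514), both chosen after the data were seen. The higher members included *hsp82*, whose call ended with a pseudocount of 0.1, and *hsp1* (GRMZM5G802801), an Hsp70 gene at 212 ± 29.0 and 113 ± 16.7 FPKM (0.91 ± 0.17, adjusted p = 0.0062). *hsp22* (1.36 ± 0.27) was also higher, and *HSF29* (GRMZM2G179802, -0.64), named after its values were seen, was lower. For *hsp101* the interval of the difference was 0.18 to 0.89 (adjusted p = 0.0611). The count of 8 was 2 with a pseudocount of 0.1, 3 with no filter, and 4 with median-of-ratios scaling or a fit of only the 2 groups. It was 3, 5, 4 and 4 without 10-OPEA replicate 1, 2, 3 or 4, and 3 without 12-OPDA replicate 2 or replicate 4.

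For glutathione transferases 2 of 24 members were higher with 10-OPEA and 22 did not pass, 4 were higher over the list alone, and the list was not called (median 0.22, adjusted p = 0.157, adjusted p = 0.641 with an estimated correlation). *gst20* stood at 3.22 ± 1.30 FPKM with 10-OPEA, and at 0.286 ± 0.224 FPKM with 12-OPDA against 0.321 ± 0.217 FPKM in control leaves. *gst8* (GRMZM2G156877, 0.80 ± 0.23, adjusted p = 0.0432) lost its call with both other scalings and without control replicate 1, any single 10-OPEA library, or 12-OPDA replicate 2, 3 or 4. It also lost it with a pseudocount of 0.1, no filter and a fit of only the 2 groups. The interval of the difference was -0.18 to 0.73 for *gst2* and -0.48 to 0.30 for *gst31*. Cytochrome P450 genes had 1 member lower and 8 that did not pass, with 3 lower over the list alone, and were not called (median -0.14 and 0.01 with quantile normalization, adjusted p = 0.0919, adjusted p = 0.485 with an estimated correlation). *cyp10* (GRMZM2G370745) differed by -1.04 ± 0.25 (adjusted p = 0.0211), a call that ended without 10-OPEA replicate 2, 3 or 4 or 12-OPDA replicate 1, 2 or 3, and with no filter. *cyp71c2* gave an interval of -1.15 to -0.25 (adjusted p = 0.0527) and passed with a filter at a mean of 5 FPKM, a fit of only the 2 groups, a robust fit with array weights, and without control replicate 1 or 3. None of 6 UDP-glycosyltransferase genes passed, over all genes or the list alone (median 0.04, and -0.01 and -0.07 with the other scalings, adjusted p = 0.971, adjusted p = 0.980 with an estimated correlation), with intervals of -0.21 to 0.79 for *bx8* (GRMZM2G085054) and -0.18 to 0.59 for *bx9*.

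Benzoxazinoid genes were lower with 10-OPEA in 2 of 13 cases and 11 did not pass, with 3 lower over the list alone and a median of -0.30 (adjusted p = 0.0234, adjusted p = 0.485 with an estimated correlation). The lower members were *BX14* (-1.73) and *Igl* (-1.16), while *bx1* gave an interval of -0.44 to 0.61 and *igl1* -0.82 to 0.10. The call ended with median-of-ratios scaling (adjusted p = 0.063), with quantile normalization (adjusted p = 0.276) and without 10-OPEA replicate 4, 12-OPDA replicate 1 or 12-OPDA replicate 2 (adjusted p = 0.059, 0.0765 and 0.0581). It also ended with fry (adjusted p = 0.0683) and without 12-OPDA replicate 3 and 10-OPEA replicate 4 together (adjusted p = 0.0634). In the terpenoid phytoalexin list 2 of 14 members were lower, *TPS8* (GRMZM2G038153, -1.62) and *tps23* (GRMZM2G127336, -1.31), and 12 did not pass, also over the list alone. Its median was -0.20 (adjusted p = 0.0201, adjusted p = 0.426 with an estimated correlation) and its call ended with quantile normalization (adjusted p = 0.0951). *tps10* gave an interval of -1.11 to 0.27. Cell wall expansion genes had 2 of 12 members lower and 10 that did not pass, with 3 lower over the list alone and a median of -0.37 (adjusted p = 0.0132, adjusted p = 0.441 with an estimated correlation). The lower members were the cellulose synthase genes *cesa2* (GRMZM2G027723, -1.08) and *cesa8* (GRMZM2G177631, -0.86). The call ended with a filter at a mean of 5 FPKM (adjusted p = 0.0511) and with fry (adjusted p = 0.0631). Cytosolic ribosomal protein genes were the only list called higher with 10-OPEA, with 4 of 30 members higher and 26 that did not pass, 10 higher over the list alone, and a median of 0.32 (adjusted p = 0.00184, adjusted p = 0.564 with an estimated correlation). *RPL19* (GRMZM5G887054, 0.61) and *RPL27A* (GRMZM2G047732, 0.92) had the smallest p-values, and with median-of-ratios scaling 1 member was higher.

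Of 6 pathogenesis-related genes *prp4* was higher with 10-OPEA (1.37 ± 0.23, adjusted p = 0.00292) and 5 did not pass, with 1 higher and 1 lower over the list alone. That list was not called (median 0.03 and -0.05 with median-of-ratios scaling, adjusted p = 0.876, adjusted p = 0.956 with an estimated correlation). The interval was -0.77 to -0.15 for *PRP* (adjusted p = 0.0660 from limma), -0.45 to 0.91 for *pr5* and -0.93 to 0.50 for *chn1*. *PRP* passed with median-of-ratios scaling, a fit of only the 2 groups, a robust fit with array weights, and without control replicate 2. *wip1* was the only 1 of 6 protease inhibitor genes that differed, also over the list alone (list median -0.07, adjusted p = 0.393, adjusted p = 0.650 with an estimated correlation). Intervals were -0.65 to 0.02 for *PIS* (GRMZM2G110646) and -1.31 to 0.20 for *MPI*. None of 15 photosystem and light-harvesting genes passed, over all genes or the list alone (median 0.11, adjusted p = 0.792, adjusted p = 0.956 with an estimated correlation), with intervals of 0.02 to 0.67 for *PSA2* and -1.20 to -0.01 for *cab48*.

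Transcription factors and small RNA precursors were among the named genes that differed between the compounds. *MYBR41* (2.37 ± 0.25) and *RADIALIS* (1.98 ± 0.30) were higher with 10-OPEA, where their levels of 14.9 ± 4.36 and 46.9 ± 13.4 FPKM lay beside control levels of 20.3 ± 3.68 and 71.4 ± 22.05 FPKM. *CIPK16* (GRMZM2G330049), a calcineurin B-like interacting kinase gene, differed by 1.66 ± 0.33. *MYBR47* differed by 1.97 ± 0.57 (adjusted p = 0.0468), a call that ended with both other scalings, a pseudocount of 5, no filter, and without control replicate 4 or any single treated library. *MYBR95* (GRMZM2G115070, -3.09 ± 0.31) and *MYBR45* (GRMZM2G415077, -2.79 ± 0.42) were higher with 12-OPDA, at 18.2 ± 10.2 and 35.5 ± 16.8 FPKM. The precursor locus *MIR156d* was listed at 20.0, 11.3, 28.6 and 71.9 FPKM in the 10-OPEA libraries and at 10.3, 0, 0 and 0 with 12-OPDA (3.90 ± 1.08, adjusted p = 0.0397). *MIR156j* was listed at 0, 0, 0 and 17.6 FPKM with 10-OPEA and at 26.7, 20.8, 24.8 and 23.7 with 12-OPDA (-3.59 ± 0.96, adjusted p = 0.0346). Both calls ended with a pseudocount of 0.1 and with no filter on low values. The *MIR156d* call ended without any single 10-OPEA library or 12-OPDA replicate 2, 3 or 4, and the *MIR156j* call without 10-OPEA replicate 1, 2 or 3 or any single 12-OPDA library.

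Marker lists for other cell types of the leaf did not pass in any comparison. None of 15 tests with camera was called, against 3 at an unadjusted p under 0.05 and 4 called with fry, which tests only whether a list's own genes move on balance one way. The 4 were mesophyll markers, lower with 10-OPEA and with 12-OPDA (fry adjusted p = 0.00452 and 0.00382), and the vascular list, higher with each (fry adjusted p = 0.00171 and 0.000451). Mesophyll markers had 1 of 5 members lower with 10-OPEA (list adjusted p = 0.0981) and 2 with 12-OPDA (adjusted p = 0.205). Bundle sheath markers had 0 of 6 called with 10-OPEA (adjusted p = 0.715) and 1 lower with 12-OPDA (adjusted p = 0.643). Epidermis and cuticle markers had 1 higher and 1 lower of 6 with 10-OPEA (adjusted p = 0.591) and 1 higher and 2 lower with 12-OPDA (adjusted p = 0.622). The vascular list had 4 of 18 higher with 10-OPEA (adjusted p = 0.100) and 7 higher and 1 lower with 12-OPDA (adjusted p = 0.0732), but most of its members are protein phosphatase genes whose symbols share its pattern. Dividing-cell markers had 1 of 10 higher with 10-OPEA (adjusted p = 0.803) and 2 lower with 12-OPDA (adjusted p = 0.591). Between the compounds the adjusted p-values of these lists were 0.938 (mesophyll), 0.713 to 0.715 (bundle sheath, epidermis), 0.308 (vascular) and 0.464 (dividing cells). Only 1 seed storage gene was measured, with changes of -0.01 and 0.57 that did not pass, and no gene of the pollen and anther list was measured.

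Over all lists and comparisons 30 of 99 tests were called with the preset correlation and 0 with an estimated correlation, where 17 had an unadjusted p under 0.05. Each compound against control gave 11 lists higher and 0 lower, and the direct comparison gave 1 higher and 7 lower. The lists overlap, so these are not counts of separate gene sets. Both lipoxygenase branches lie within oxylipin biosynthesis, and *cyp71c2*, *CYP71C3*, *bx8* and *bx9* are also benzoxazinoid members. In 6 of 99 other groupings of the 12 libraries at least 30 lists were called.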

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

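The tests of library scaling and of single libraries on heat shock and jasmonate genes were chosen after their result was seen. Single libraries stood far from the other 3 of their group in 15 of 201 groups of values, where 10.05 would be expected by chance.

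In many of these the values lay near 0. *hsp18c* was at 0.246 FPKM in control replicate 1 and *prp4* at 0.263 FPKM in the same library, against 0 in the others. *JAZ9* was at 0.326 FPKM in control replicate 4, against 0 in the others, and *MYBR95* at 0.133 FPKM in that library. *MYBR95* was also at 0.381 FPKM in 10-OPEA replicate 4, against 1.18 to 1.37 in the others. *ciszog1* was at 3.7e-07 FPKM in control replicate 3, against 1.03 to 1.22, and *gst20* at 0 FPKM in control replicate 2, against 0.383 to 0.455. *MIR156d* was at 10.3 FPKM in 12-OPDA replicate 1, against 0 in the others. *MIR156j* was at 12.7 FPKM in control replicate 4 and 17.6 FPKM in 10-OPEA replicate 4, against 0 in the others of each group. Among more abundant transcripts, *bx1* was at 135 FPKM in 10-OPEA replicate 2, against 241 to 248, and *tps10* at 96.8 FPKM in 10-OPEA replicate 4, against 132 to 138. *dhn2* was at 23.1 FPKM in 12-OPDA replicate 3, against 12.2 to 13.3, and *PRP* at 62.6 FPKM in that library, against 71.7 to 72.2. The FPKM sum of 10-OPEA replicate 1 was 766140, against 691455 to 702611. Replicate 1 also had the highest sum of its group for control (800109) and for 12-OPDA (797414). No cause was tested for these values.

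Other assignments of the libraries to groups gave far fewer calls for each comparison. Of 35 splits of the 8 libraries, 1, the real one, gave as many genes as 5516 for 10-OPEA (highest other 2). The real split was also the only 1 to reach 8443 for 12-OPDA (highest other 1) and 1587 between the compounds (highest other 2). Every other split mixed libraries of both groups, which put the real difference into the spread and held its count down. The 35 splits alone therefore cannot exclude chance for these counts. For genes called with both compounds 1 of 100 groupings, the real one, gave 4789, and the highest other, 4646, kept all 4 controls together. Only 1 drawn grouping did so, and its other groups mixed the compounds. The rank therefore bears on control against treated libraries and not on a response shared by the compounds. For gene lists 7 of 100 groupings, the real one included, gave at least 30 called lists, with a highest other of 38, so chance is not excluded for that count. The 6 others all kept at least 3 controls together, and the median of the other groupings was 17.

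Among 1200 genes that differed between the compounds, were called with at least 1 of them and had estimates of the same sign against control, the estimate was larger with 12-OPDA for 1098. The share larger with 12-OPDA was 92.2% with quantile normalization and 94.2% with median-of-ratios scaling, against 91.5% as reported. These scalings moved the median difference of all genes between the compounds by only -0.052 and -0.067 log2 units, so a larger scaling error was not tested. The tables argue against the choice among these scalings as the cause. They argue against the lower depth of the 12-OPDA libraries, since the share was 94.1% among 204 genes with a mean of at least 50 FPKM. With 1 common factor between the responses on the log2 scale, 16.25% of the 1200 genes still differed at the factor that left the fewest, 0.6. These genes were picked because they differed without a factor. Over all genes 1086 differed at 0.6 and at least 745, at 0.75, over the factors tried. Unequal dose, uptake or timing need not change all genes by 1 factor, so this test cannot limit their share. They may account for part or all of this pattern and stay open beside a difference between the compounds.

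Between the compounds 4 of 9 jasmonate signalling genes and 9 of 21 oxylipin genes were lower with 10-OPEA (medians -1.06 and -0.45), list calls that ended with an estimated correlation (adjusted p = 0.232 and 0.485 with camera), while the heat shock median was 0.41 in a list that was not called (adjusted p = 0.0525). Under the other scalings all 3 medians kept their sign and lay at least 0.34 from 0. Without each of the 12 libraries the smallest distance was 0.309. These values argue against the choice among these scalings, or a single library, as the cause of the opposite signs. Median-of-ratios scaling and quantile normalization moved the median difference of all genes by only -0.067 and -0.052 log2 units. A larger scaling error was therefore not tested. A difference between the compounds in the balance of these responses is a hypothesis that may be put to matched doses and times, and reads shared between related genes were not tested.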

How the results depend on the processing

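Settings chosen after the data were seen were fry, the 2 changed sets of lists and the joint omission of 12-OPDA replicate 3 and 10-OPEA replicate 4. No called named gene and no called list turned direction, but the balance of directions among called genes turned in each comparison. It turned with quantile normalization for 10-OPEA (2732 up, 4145 down). For 12-OPDA it turned with median-of-ratios scaling (4650 up, 3750 down), a mean of at least 5 FPKM (2942 and 2936), and at least 2-fold change (2263 and 1223). It also turned for 12-OPDA without control replicate 2 (3700 and 3605), control replicate 3 (4138 and 4113) or 12-OPDA replicate 1 (3871 and 3733). Between the compounds it turned with array weights (1375 higher, 1183 lower), replicate blocks (1367 and 1066), a pseudocount of 0.1 (685 and 667), and without 12-OPDA replicate 1 (783 and 749) or 2 (630 and 622). Over the alternatives in scaling, pseudocount, filter and model, counts for each compound against control and for both compounds stayed within 1.5 times the reported values. Leaving out 1 library gave 4322 to 5589 genes for 10-OPEA, 7305 to 8416 for 12-OPDA and 3841 to 4832 for both. The count between the compounds, 1587, moved more: 2558 with a robust fit and array weights, 2433 with replicate blocks, 930 to 1756 without 1 library, and 593 without the joint pair. Fewer samples enter the last settings, and for the others the cause was not tested. The labels do not say what replicate numbers share: 8 of 12 same-number pairs correlated above 0.1 (-0.0849 to 0.522) and 6 of 12 libraries correlated best with their own number, so a shared factor stays possible for some numbers. Pairs of number 1 correlated at 0.305 to 0.522 and of number 4 at 0.209 to 0.291. Pairs of number 2 gave -0.0849 to 0.107 and of number 3 -0.0210 to 0.103. With blocks the call of the 9-lipoxygenase list between the compounds (adjusted p = 0.0777 with camera) and that of *MYBR47* ended, and *opr8* with 10-OPEA and *cyp71c2*, *PRP* and *ts1* between the compounds passed. Requiring at least 2-fold change, a stricter rule by construction, left 2287 genes for 10-OPEA, 3486 for 12-OPDA, 569 between the compounds and 1970 in both. Called lists numbered 30, then 0 with an estimated correlation (17 at an unadjusted p under 0.05) and 57 with fry, which asks another question. Without members of other gene families 33 of 96 tests were called, 24 higher and 9 lower, and all 30 calls were kept. With the longer lists 34 were called. Marker lists gave 0, then 1 with no filter, 0 to 2 without 1 library (2 without control replicate 3) and 4 with fry. The cause was not tested for the change with no filter. Named gene values without 1 library kept direction and side of the threshold in 1227 of 1284 cases, lost the call in 50, gained it in 4 and moved in 3. Called lists did so in 353 of 360 cases and lost the call in 7. The count-based alternative was not run because the table holds no counts. Only relative depth is known, so the limit it sets on genes near 0 cannot be stated.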

Other observations

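The genes in this part were chosen after their values were seen. The alternative oxidase genes *aox1* (GRMZM2G125669) and *aox3* (GRMZM2G074743) rose by 3.75 and 4.21 with 10-OPEA and by 3.96 and 5.55 with 12-OPDA on the log2 scale, and their list has too few measured members for a test. *WRKY53* (GRMZM2G125653) rose by 3.12 and 3.28 and *WRKY43* (GRMZM2G148087) by 2.70 and 2.91, in a list that was not called (3 of 10 higher with 10-OPEA, 3 higher and 2 lower with 12-OPDA, adjusted p = 0.205 and 0.499). Among senescence genes *lls1* (GRMZM2G339563) rose by 1.63 and 1.78, while *see2b* (GRMZM2G093032) had changes of -1.45 and -2.26, in a list with 2 of 5 members higher and 2 lower with each compound that was not called (adjusted p = 0.896 and 0.971). The ethylene synthesis gene *ACO31* (GRMZM2G072529) rose from 5.12 ± 2.52 to 38.9 ± 11.9 FPKM with 10-OPEA and 149 ± 29.7 FPKM with 12-OPDA, a difference between the compounds of -1.94 ± 0.29 (adjusted p = 0.00142), and the ethylene list was not called between them (2 of 5 lower, adjusted p = 0.189).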
